A study of Homo sapiens with 6 samples.

How the data were processed

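Gene expression was measured by RNA sequencing in 6 libraries of SW1353 cells, 3 with a scrambled hairpin and 3 with a hairpin against JAB1. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the TruSeq Stranded Total RNA kit with Ribo-Zero Gold, and single-end reads were sequenced on HiSeq instruments. Per the submitters' processing notes, STAR, Cufflinks and Cuffdiff were used with the GRCh38 build, and the extraction protocol also names CLC Genomics Workbench. Tool versions, the annotation release and whether counting used strand are not given in the sources used here, so reads of overlapping and antisense genes may not be separable.

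The deposited table held Cuffdiff's values per library. The authors' expected counts (raw fragments per gene, estimated and not always whole) were used for the main test, rounded to whole numbers, and the authors' deposited FPKM values, normalized by Cuffdiff, served for alternatives. Of all values 9.65% were not whole, and of those above 0 in a library 19.5% to 20.6%, which marks genes that share reads with others. Of the 19279 genes tested, 7284 (37.8%) had a count that was not whole in at least 1 library. The table calls its conditions NTC and KD, words that differ from those of the labels' descriptions. KD was matched to the genotype label of the JAB1 hairpin, NTC was assigned to the one group left, the scrambled control, and libraries within a group were matched by replicate number. The table held 58024 genes, of which 53675 had the same versioned identifier in GENCODE 29 and 57420 matched without the version; coordinates are on GRCh38. Cuffdiff had skipped 71 genes in at least 1 library for too many fragments and listed them at 0, 62 in all libraries, 8 in the controls alone (ACTB among them) and 1 in the knockdown libraries alone. These were left out. Total counts per library were 27123099, 26770476 and 30282205 fragments in the controls and 27183571, 25019467 and 24940941 after knockdown, so for abundant genes the spread between libraries and not counting limited precision.

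Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, group only) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A change of at least 2-fold needed in addition an absolute log2 fold change of 1. CPM values are TMM-scaled. COPS5 also had an exact two-sided permutation test. The 43 gene lists were fixed before the data were examined, and the 41 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation, fry and camera on ranks were run beside it. Ratios of genes with at most 3 counts in a group carry exact 95% intervals (Clopper-Pearson on the split of the summed counts), which cover counting error only.

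Named genes followed a rule set before the data were examined. It took every COP9 signalosome subunit, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a clone, pseudogene or antisense name. It also took up to 4 members of each list with the smallest adjusted p, and the 5 smallest p-values. The largest changes under the GC offset were added after their values were seen. Some genes and 1 list that the rule took are not reported here, although counts over genes and lists include them.

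After the fold changes were seen to follow GC content, a GC offset was added. For each library a loess curve (span 0.3, 4 iterations, genes with an average log2 CPM above 1) of the deviation of log2 CPM on the GC content of the mature principal transcript was used as an offset in the edgeR fit. The definition of GC content was also chosen after looking at the data: the longest transcript was tried first and replaced, because that of COPS5 was a form with a retained intron. The mean GC content over all transcripts was kept as an alternative. The other alternatives were RLE, upper-quartile and total-count scaling, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 and without that filter. The replicate number as a block, leaving out each library, an adjusted p of 0.01 and glmTreat against a fold of 1.5 completed the set chosen before the data were examined. Offsets for GC and length, the GC offset with the block, protein-coding genes only and genes with whole counts only were added after seeing the data.

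The procedure was tested on simulated data, for knockdown against control. These were made from the mean of each gene in the controls and the library sizes of all libraries. Without a GC trend (17955 genes) it recovered 94% of 2-fold and 100% of 4-fold changes and called 9 unchanged genes. With the GC trend of the real libraries (18080 genes) it recovered 64% and 92% and called 13428 unchanged genes without the offset, and 93% and 100% with 9 unchanged genes called with the offset. A real response that itself follows GC content would be removed by the offset, a case the simulation did not hold.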

Results

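RNA was sequenced from SW1353 cells, an established human chondrosarcoma line, after lentiviral delivery of short hairpin RNAs. The series compared 3 libraries from cells with a scrambled control hairpin with 3 libraries from cells with a hairpin against JAB1, the product of COPS5 and the deneddylating subunit of the COP9 signalosome, which removes NEDD8 from cullin ubiquitin ligases. Its title states the question as the role of JAB1 in chondrosarcoma. Cells were infected at a multiplicity of 5, and after 48 hours were kept for 72 hours in 2 µg/mL puromycin. The libraries held 24940941 to 30282205 estimated fragments on genes. Within a group the Pearson correlation of log2 CPM across genes was 0.981 to 0.994, and between groups it was 0.609 to 0.69. The lowest within a group were those of knockdown replicate 2 with replicates 0 (0.982) and 1 (0.981). Genes are not independent replicates, so these values describe the libraries only. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

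COPS5 (ENSG00000121022.13, GRCh38 chromosome 8, 67043079 to 67083783, minus strand) fell in the knockdown libraries. Its level was 65.3 ± 3.98 CPM in the controls and 44.7 ± 5.75 CPM after knockdown (mean ± SD, n = 3 each). By library it was 69.1, 61.1 and 65.6 CPM in the controls and 41.0, 41.9 and 51.4 CPM after knockdown. The log2 fold change was -0.55 ± 0.11 (SE, edgeR adjusted p = 0.000564). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. When each library's trend on transcript GC content was removed, the log2 fold change was -1.40 ± 0.10 (adjusted p = 3.9e-07). With an offset from the mean GC of all transcripts it was -1.19, and with GC and length -1.74. In limma on FPKM it was -0.77 to -0.75. The size of the fall thus depended on the setting, beyond the SE. Some COPS5 counts were fractional, so part of its reads was shared with other features.

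Of the other COP9 signalosome subunits, COPS2, COPS3 and COPS9 rose with and without the GC offset. The log2 fold changes were 2.98 and 0.62 for COPS2, 1.24 and 0.53 for COPS3, and 0.95 and 1.55 for COPS9, the value without the offset first. With an offset from the mean GC of all transcripts COPS3 was 0.11 (adjusted p = 0.211). GPS1 fell by 1.66 and COPS8 rose by 1.25 without the offset, while with it they were 0.02 (adjusted p = 0.811) and -0.05 (adjusted p = 0.543). COPS4 was called in opposite directions (0.93 and -0.27), as was COPS7A (-0.32 and 0.48), whose call without the offset was lost under DESeq2 (adjusted p = 0.0725). COPS6 was 0.05 without the offset (adjusted p = 0.671) and 0.83 with it, and COPS7B was -0.12 (adjusted p = 0.333) and 0.42, with 0.00 under scaling by library totals alone. The subunits as a list numbered 5 higher and 3 lower of 10 tested (5 higher and 3 lower adjusted over the list alone), and 6 higher and 2 lower with the GC offset. For cop9 signalosome the median was 0.49 (camera adjusted p = 0.198), and 0.45 with the offset (adjusted p = 0.151).

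**Figure D1:**
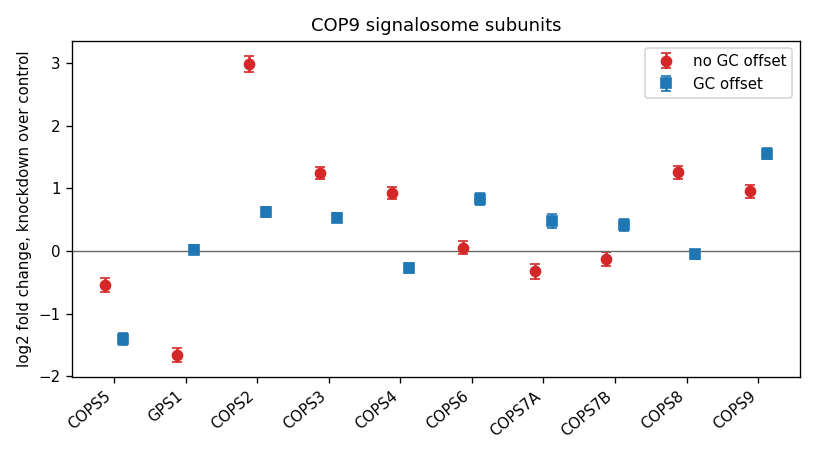
Log2 fold change (knockdown over control) of the 10 COP9 signalosome subunits, with (squares) and without (circles) an offset for transcript GC content. Bars are SE from edgeR, 3 libraries per group. COPS5 lies below 0 in both, at -0.55 and -1.40, whereas GPS1 moves from -1.66 to 0.02.

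Across the transcriptome 14692 of 19279 tested genes (76.2%) passed an adjusted p of 0.05, 7151 higher and 7541 lower after knockdown, and 10594 of them changed at least 2-fold. In 15322 genes (79.5%, where chance gives 10%) the groups did not overlap. The median log2 fold change of all genes was -0.019, and 0.107 when libraries were scaled by their totals alone. The fold changes followed the GC content of the transcript. Over 11259 protein-coding genes the Spearman correlation across genes was -0.84. The median log2 fold change was 1.95 in the decile of genes with the lowest GC content and -1.72 in the decile with the highest. Individual libraries showed slopes from 0.618 to 0.792 log2 units per 10% GC in the controls and from -0.72 to -0.645 after knockdown. Slopes were taken relative to the midpoint of the groups. Opposite mean slopes are thus given by construction and do not show which group carries the trend. Within each group the libraries shared a slope of one sign. On simulated libraries carrying this trend, the test without an offset called 75.2% of the genes simulated as unchanged, and with the GC offset it called 0.0504%. The simulated trend was the curve that the offset had fitted to the real libraries, with less scatter (Spearman -0.98). Its removal was thus given in advance, and the simulation does not tell how many real calls under the offset are true. On the real libraries the GC offset, an alternative chosen after seeing the data, left 11939 of 19169 genes past the threshold (5618 higher and 6321 lower) with 5786 changed at least 2-fold. In both fits 8015 genes passed in the same direction, 3486 higher and 4529 lower, and 1925 passed in opposite directions. At least 2-fold in both, in the same direction, were 1321 higher and 2658 lower genes. Below, a pair of values in parentheses after a gene gives its log2 fold change without and then with the GC offset.

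**Figure D2:**
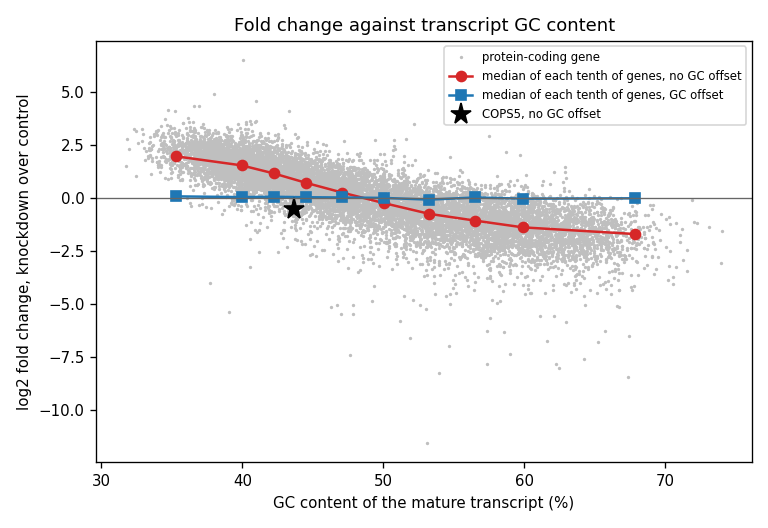
Log2 fold change (knockdown over control) against the GC content of the mature transcript in percent, for 11259 protein-coding genes (grey), with the median of each GC decile without (red circles) and with (blue squares) the GC offset. The star is COPS5 without the offset; red medians run from 1.95 to -1.72.

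Cartilage matrix genes fell, with the lowest median of the 43 lists. Type II collagen COL2A1, the main collagen of cartilage, went from 324 ± 31.4 CPM to 1.40 ± 0.171 CPM (mean ± SD, n = 3 each; log2 fold change -7.86 ± 0.15 SE, adjusted p = 4.74e-13, -6.31 with the GC offset). Type IX collagen COL9A1 went from 177 ± 5.56 to 1.03 ± 0.285 CPM (-7.43, -7.58) and the proteoglycan aggrecan, ACAN, from 196 ± 22.5 to 3.84 ± 0.261 CPM (-5.67, -4.49). Cartilage oligomeric matrix protein fell likewise, COMP (-7.62, -5.96). All 19 tested members of the cartilage matrix list fell in both fits and when adjusted over the list alone. For cartilage matrix genes the median log2 fold change was -4.51 (camera adjusted p = 2.48e-18, and adjusted p = 0.0795 with an estimated correlation). Among cartilage matrix genes the offset gave a median of -4.10 (adjusted p = 1.1e-37, and adjusted p = 0.0114 with an estimated correlation). Muscle markers were lower beside them, with a median of -3.70 and of -2.51 with the offset, and epithelial markers had -2.32 and -1.21. With an estimated correlation neither passed (adjusted p = 0.233 for muscle, 0.16 with the offset, and 0.475 for epithelial markers, 0.419 with the offset). Endothelial, immune and neural markers, with medians of -0.42, -0.70 and -0.32, did not pass camera in either fit. They passed fry in both (adjusted p = 0.000147, 0.00336 and 0.000463 without the offset).

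Genes of fibrillar and connective tissue matrix were mostly lower. COL1A2, a chain of type I collagen, went from 3828 ± 199 to 117 ± 11.2 CPM (-5.03, -4.16). Tenascin C, TNC (-3.10, -2.32), the small proteoglycan biglycan, BGN (-5.57, -4.08), and COL5A1 (-3.25, -1.83) fell as well. The list numbered 3 higher and 25 lower of 31 tested (3 higher and 25 lower adjusted over the list alone), and 1 higher and 29 lower with the GC offset. For connective matrix genes the median log2 fold change was -2.21 (camera adjusted p = 2.85e-11, and adjusted p = 0.233 with an estimated correlation). Among connective matrix genes the offset gave a median of -1.45 (adjusted p = 1.18e-16, and adjusted p = 0.0661 with an estimated correlation). Matrix proteases and inhibitors numbered 6 higher and 13 lower of 23 tested (6 higher and 13 lower adjusted over the list alone), and 6 higher and 10 lower with the GC offset. For matrix proteases the median was -0.77 (camera adjusted p = 0.198), and -0.48 with the offset (adjusted p = 0.151). Members that fell included TIMP2 (-2.66, -1.91), MMP14 (-2.36, -1.06), MMP3 (-1.96, -2.60) and CTSB (-1.65, -1.02). The highest log2 fold change in the protease list was the rise of MMP1 (4.10, 3.20). Hypertrophic and osteoblast genes numbered 5 higher and 6 lower of 12 tested (5 higher and 6 lower adjusted over the list alone), and 2 higher and 6 lower with the GC offset. For osteoblast genes the median was -0.07 (camera adjusted p = 0.823), and -0.45 with the offset (adjusted p = 0.409). The examples are PTH1R (-3.94, -2.42), DLX5 (-1.73, -0.95), ALPL (-2.44, -1.09) and PHEX (1.49, 0.08), the last with adjusted p = 0.666 under the offset.

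**Figure D3:**
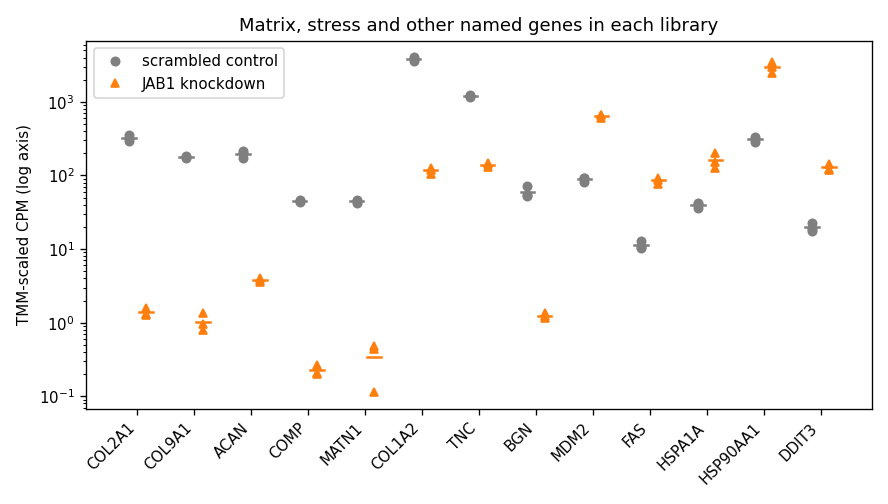
TMM-scaled CPM (log axis) of matrix, stress and other named genes in each of the 3 control (circles) and 3 knockdown (triangles) libraries, with bars at group means. COL2A1 averages 324 CPM in the controls and 1.40 CPM after knockdown, and MDM2 89.5 and 637 CPM.

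Among other named genes, the ubiquitin ligase MDM2 rose from 89.5 ± 6.46 to 637 ± 35.3 CPM (mean ± SD, n = 3 each; log2 fold change 2.83 ± 0.10 SE, adjusted p = 3.52e-11, 1.65 with the GC offset). The death receptor FAS (2.91, 1.31) and the ribonucleotide reductase subunit RRM2B (3.15, 1.17) rose too, while PLXNB2 fell (-2.78, -1.17).

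Heat-shock genes were more often higher than lower. HSP90AA1, a cytosolic HSP90 chaperone, rose from 311 ± 21.1 to 2982 ± 524 CPM (3.26, 2.29). HSPH1 (2.19, 0.71) and the mitochondrial chaperonin HSPD1 (2.09, 1.35) rose and the small heat-shock protein HSPB1 fell (-2.50, -0.81). Their list numbered 10 higher and 4 lower of 15 tested (10 higher and 4 lower adjusted over the list alone), and 11 higher and 3 lower with the GC offset. For heat-shock genes the median log2 fold change was 1.21 (camera adjusted p = 0.0189, and adjusted p = 0.233 with an estimated correlation). Among heat-shock genes the offset gave a median of 0.88 (adjusted p = 4.2e-05, and adjusted p = 0.0868 with an estimated correlation). Proteasome subunits numbered 20 higher and 4 lower of 33 tested (20 higher and 4 lower adjusted over the list alone), and 22 higher and 5 lower with the GC offset. For proteasome subunits the median log2 fold change was 0.62 (camera adjusted p = 0.00587, and adjusted p = 0.233 with an estimated correlation). Among proteasome subunits the offset gave a median of 0.43 (adjusted p = 0.00123, and adjusted p = 0.214 with an estimated correlation). PSMD14, the proteasomal deubiquitinase, rose (1.83, 1.29), as did PSMA3 (1.62, 0.25) and PSMA4 (1.496, 0.37). PSMC6 rose without the offset (2.02, 0.08). With the mean GC of all transcripts, PSMA3 was -0.04 and PSMA4 -0.11, and with GC and length PSMA3 was -0.26 (adjusted p = 0.00711). Ribosomal proteins numbered 37 higher and 9 lower of 58 tested (37 higher and 9 lower adjusted over the list alone), and 42 higher and 5 lower with the GC offset. For ribosomal proteins the median log2 fold change was 0.44 (camera adjusted p = 0.0296, and adjusted p = 0.643 with an estimated correlation). Examples were RPL26 (1.05, 1.07), RPS24 (1.04, 0.89), RPL6 (1.08, 0.91) and RPL14 (0.96, 0.21), of which RPL26 was 0.14 (adjusted p = 0.147) with the mean GC of all transcripts. Among ribosomal proteins the offset gave a median of 0.79 (adjusted p = 1.04e-13, and adjusted p = 0.114 with an estimated correlation). Ribosomal protein genes have processed copies, and the counts of RPL26 and RPL6 were not all whole, so their values are uncertain. Ribosome biogenesis and MYC target genes numbered 14 higher and 14 lower of 30 tested (14 higher and 14 lower adjusted over the list alone), and 18 higher and 5 lower with the GC offset. Without the offset this list did not pass (median 0.11, camera adjusted p = 0.48). Among ribosome biogenesis myc the offset gave a median of 0.52 (adjusted p = 0.0019, and adjusted p = 0.419 with an estimated correlation). NOP58 (2.44, 1.17) and GNL3 (1.87, 1.04) were higher and CAD (-2.24, -1.05) was lower.

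Genes of fatty acid synthesis and of cholesterol synthesis were more often lower than higher. The fatty acid desaturase SCD went from 845 ± 24.3 to 116 ± 9.67 CPM (-2.86, -3.09), with falls of the transcription factor SREBF1 (-4.34, -2.63), fatty acid synthase FASN (-3.73, -1.97) and FADS2 (-2.93, -1.49). Fatty acid synthesis numbered 3 higher and 8 lower of 12 tested (3 higher and 8 lower adjusted over the list alone), and 2 higher and 10 lower with the GC offset. For fatty acid genes the median log2 fold change was -0.88 (camera adjusted p = 0.01, and adjusted p = 0.233 with an estimated correlation). Among fatty acid genes the offset gave a median of -1.10 (adjusted p = 6.82e-07, and adjusted p = 0.0661 with an estimated correlation). Cholesterol synthesis numbered 8 higher and 15 lower of 25 tested (8 higher and 15 lower adjusted over the list alone), and 3 higher and 18 lower with the GC offset. For cholesterol genes the median log2 fold change was -0.74 (camera adjusted p = 0.016, and adjusted p = 0.518 with an estimated correlation). Among cholesterol genes the offset gave a median of -0.61 (adjusted p = 0.000443, and adjusted p = 0.343 with an estimated correlation). The examples are LSS (-3.20, -1.96), DHCR7 (-3.23, -1.99) and SREBF2 (-2.61, -1.39). Hypoxia and glycolysis genes numbered 7 higher and 21 lower of 30 tested (8 higher and 21 lower adjusted over the list alone), and 4 higher and 20 lower with the GC offset. For glycolysis genes the median log2 fold change was -1.06 (camera adjusted p = 0.00587, and adjusted p = 0.403 with an estimated correlation). Falls included PFKL (-2.77, -1.13), EGLN3 (-2.64, -2.98), ALDOA (-2.02, -0.61) and PFKFB3 (-1.84, -0.87). Among glycolysis genes the offset gave a median of -0.54 (adjusted p = 0.00218, and adjusted p = 0.357 with an estimated correlation). NRF2 targets numbered 6 higher and 17 lower of 27 tested (6 higher and 17 lower adjusted over the list alone), and 7 higher and 14 lower with the GC offset. For NRF2 targets the median was -0.45 (camera adjusted p = 0.146), and -0.36 with the offset (adjusted p = 0.115). Falls included the pentose phosphate enzymes TKT (-2.37, -1.15) and PGD (-2.07, -1.44), and AKR1B1 (-1.71, -0.999). Nuclear genes of oxidative phosphorylation numbered 21 higher and 13 lower of 44 tested (21 higher and 13 lower adjusted over the list alone), and 25 higher and 15 lower with the GC offset. These did not pass without the offset (median 0.29, camera adjusted p = 0.247). Among oxidative phosphorylation nuclear the offset gave a median of 0.42 (adjusted p = 0.00564, and adjusted p = 0.634 with an estimated correlation). That call ended with GC and length (median 0.01, adjusted p = 0.921) and with the mean GC of all transcripts (adjusted p = 0.0865). NDUFA5 (2.64, 0.65) and SDHD (1.67, 0.35) were higher and NDUFV1 (-1.88, -0.54) and SDHA (-1.27, -0.35) lower, and SDHD was 0.00 with an offset for GC and length. Mitochondrially encoded genes numbered 13 higher and 0 lower of 13 tested (13 higher and 0 lower adjusted over the list alone), and 9 higher and 1 lower with the GC offset. For mitochondrially encoded genes the median log2 fold change was 1.21 (camera adjusted p = 0.00587, and adjusted p = 0.526 with an estimated correlation). Examples were MT-ND2 (1.95, 0.97), MT-CO1 (1.17, 0.80), MT-CO3 (1.20, 0.88) and MT-CYB (1.60, 1.24). Among mitochondrially encoded genes the offset gave a median of 0.80 (adjusted p = 0.0481, and adjusted p = 0.642 with an estimated correlation). Their share of fragments on genes that Cuffdiff had not skipped was 0.172% to 0.233% in the controls and 0.447% to 0.496% after knockdown.

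Wnt target genes were more often lower than higher. AXIN2, the feedback inhibitor of the pathway, (-2.86, -2.20), NKD1 (-2.87, -2.40), FZD7 (-2.64, -2.01) and NOTUM (-5.04, -3.27) were lower, and the list numbered 2 higher and 10 lower of 14 tested (2 higher and 10 lower adjusted over the list alone), and 1 higher and 9 lower with the GC offset. The highest log2 fold change in the Wnt list was 5.68, and 4.92 with the offset. For Wnt targets the median log2 fold change was -1.79 (camera adjusted p = 0.00587, and adjusted p = 0.233 with an estimated correlation). Among Wnt targets the offset gave a median of -0.97 (adjusted p = 0.0022, and adjusted p = 0.195 with an estimated correlation). TGF-beta targets numbered 6 higher and 14 lower of 21 tested (6 higher and 14 lower adjusted over the list alone), and 4 higher and 10 lower with the GC offset. For TGF-beta targets the median log2 fold change was -0.82 (camera adjusted p = 0.0468, and adjusted p = 0.296 with an estimated correlation). Falls included CNN1 (-4.11, -2.73), ITGA11 (-3.39, -2.22), TGFB3 (-3.14, -2.46) and TGFB1 (-2.89, -1.25). Among TGF-beta targets the offset gave a median of -0.36 (adjusted p = 0.0199, and adjusted p = 0.195 with an estimated correlation). YAP targets numbered 3 higher and 16 lower of 22 tested (3 higher and 16 lower adjusted over the list alone), and 4 higher and 13 lower with the GC offset. For YAP targets the median log2 fold change was -0.71 (camera adjusted p = 0.0468, and adjusted p = 0.403 with an estimated correlation). AMOTL2 (-1.93, -0.76), AXL (-2.19, -1.42) and ARHGEF17 (-2.18, -0.58) were lower and NT5E (1.80, 0.72) was higher, and ARHGEF17 was -0.25 (adjusted p = 0.085) with GC and length. Among YAP targets the offset gave a median of -0.57 (adjusted p = 0.00946, and adjusted p = 0.186 with an estimated correlation). Neither list passed without control replicate 0 (adjusted p = 0.0516 for both) or without knockdown replicate 0 (adjusted p = 0.0726 for TGF-beta and 0.0662 for YAP targets), nor with RLE factors (adjusted p = 0.0508 for both). The same held for library totals (adjusted p = 0.0503 and 0.0623), the stricter filter (adjusted p = 0.0733 for both) and protein-coding genes only (adjusted p = 0.0891 for both). Over these settings the medians lay between -0.83 and -0.70 for TGF-beta and between -0.71 and -0.59 for YAP targets. With the mean GC of all transcripts the TGF-beta list passed with a median of -0.05 (adjusted p = 0.0382). With GC and length the TGF-beta median was -0.12 (adjusted p = 0.0609) and the YAP median -0.40 (adjusted p = 0.0655). BMP components and targets numbered 10 higher and 13 lower of 29 tested (10 higher and 13 lower adjusted over the list alone), and 6 higher and 14 lower with the GC offset. For BMP genes the median was -0.14 (camera adjusted p = 0.515), and -0.37 with the offset (adjusted p = 0.332). BMP1 (-2.43, -0.85) and ID3 (-1.70, -0.57) were lower and SMURF2 (1.66, 0.97) was higher, although SMURF2 was 0.17 (adjusted p = 0.13) with the mean GC of all transcripts. SMAD5 was higher without the offset and not with it (1.78, -0.14). It kept its call with GC and length and with the mean GC of all transcripts. AP-1 and immediate early genes numbered 9 higher and 10 lower of 25 tested (10 higher and 10 lower adjusted over the list alone), and 15 higher and 3 lower with the GC offset. Their median was 0.06 where the mean was -0.22 (camera adjusted p = 0.597), and they passed as higher only under the offset (median 0.57, adjusted p = 0.0147, and adjusted p = 0.195 with an estimated correlation). SPRY2 was higher (2.08, 2.04), FOSL2 (-2.80, -2.10) and IER2 (-2.40, -0.89) were lower, and JUND was lower without the offset and not with it (-2.02, -0.02). JUND kept its call with GC and length and lost it with the mean GC of all transcripts. NF-kappaB and inflammatory genes numbered 7 higher and 6 lower of 17 tested (7 higher and 6 lower adjusted over the list alone), and 6 higher and 5 lower with the GC offset. For inflammatory genes the median was 0.14 (camera adjusted p = 0.901), and 0.50 with the offset (adjusted p = 0.355). CXCL8 (4.36, 1.99) and TNFAIP3 (1.52, 1.66) were higher, TNFAIP2 (-2.20, -0.66) was lower and NFKB2 was lower without the offset only (-1.54, -0.05). Interferon-stimulated genes numbered 12 higher and 13 lower of 30 tested (12 higher and 13 lower adjusted over the list alone), and 7 higher and 14 lower with the GC offset. For interferon genes the median was -0.31 (camera adjusted p = 0.823), and -0.22 with the offset (adjusted p = 0.406). STAT2 (-1.99, -1.53) and IFI6 (-1.88, -0.85) were lower, DDX58 (2.36, 0.96) was higher and IFIT5 was higher without the offset only (1.94, 0.09).

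Genes of G2 and mitosis were more often higher than lower. The kinase TTK (2.67, 0.70), ECT2 (2.65, 0.88), ANLN (2.41, 0.93) and DLGAP5 (2.50, 0.78) were higher, and the G2 and mitosis list numbered 28 higher and 7 lower of 40 tested (28 higher and 7 lower adjusted over the list alone), and 20 higher and 2 lower with the GC offset. For mitotic genes the median log2 fold change was 1.01 (camera adjusted p = 0.00142, and adjusted p = 0.662 with an estimated correlation). Among mitotic genes the offset gave a median of 0.33 (adjusted p = 0.0113, and adjusted p = 0.733 with an estimated correlation). The call ended with the mean GC of all transcripts (median 0.21, adjusted p = 0.0865). Replication genes numbered 15 higher and 17 lower of 44 tested (15 higher and 17 lower adjusted over the list alone), and 13 higher and 16 lower with the GC offset. For replication genes the median was -0.13 (camera adjusted p = 0.515), and -0.06 with the offset (adjusted p = 0.789). Falls included the helicase subunits MCM2 (-2.42, -1.20) and MCM5 (-1.99, -0.92), the methyltransferase DNMT1 (-1.79, -0.84) and E2F2 (-3.12, -1.96). G1 cyclins and inhibitors numbered 6 higher and 6 lower of 16 tested (6 higher and 6 lower adjusted over the list alone), and 6 higher and 5 lower with the GC offset. For G1 regulators the median was 0.09 (camera adjusted p = 0.741), and 0.10 with the offset (adjusted p = 0.357). CCND1, cyclin D1, rose (0.89, 1.16), RB1 (1.36, -0.52) and CCND3 (-1.10, 0.30) were called in opposite directions, and RBL1 was higher without the offset only (1.67, 0.20). RB1 was 0.02 (adjusted p = 0.854) with the mean GC of all transcripts and CCND3 0.16 (adjusted p = 0.133) with GC and length. RBL1 kept its call as higher with either of these offsets. Replication-dependent histone genes, a family of similar copies of which 50 of the 53 tested had whole counts in every library, numbered 0 higher and 26 lower of 53 tested (0 higher and 25 lower adjusted over the list alone), and 20 higher and 22 lower with the GC offset. For histone genes the median log2 fold change was -0.67 (camera adjusted p = 0.00461, and adjusted p = 0.662 with an estimated correlation). The call on histones was lost under the offset (median -0.16, adjusted p = 0.355) and held with GC and length (median -0.45, adjusted p = 0.000474). With the mean GC of all transcripts the histone median was 0.11 (adjusted p = 0.401). HIST1H4I fell (-5.04, -5.33), with HIST1H4D (-7.87, -6.76) and HIST1H4L (-7.40, -6.12). Without knockdown replicate 0 HIST1H4D was -9.02 and HIST1H4L -8.27. HIST2H3D had 1184 counts over the controls and 3 over the knockdown libraries, a ratio of 394 with an exact 95% interval of 135 to 1910 that covers counting error only. Without knockdown replicate 1, which held 2 of the 3 counts, the ratio was 794 (142 to 31400). DNA damage repair genes numbered 22 higher and 7 lower of 33 tested (22 higher and 7 lower adjusted over the list alone), and 21 higher and 8 lower with the GC offset. For repair genes the median log2 fold change was 1.56 (camera adjusted p = 0.000143, and adjusted p = 0.48 with an estimated correlation). XRCC2 (2.85, 1.79), POLQ (2.31, 1.003), LIG4 (2.95, 0.93) and ATM (1.90, 0.28) were higher, and ATM was 0.07 (adjusted p = 0.471) with the mean GC of all transcripts. The repair call was lost under the offset (adjusted p = 0.059, median 0.39) and held with GC and length (median 0.52, adjusted p = 0.00154). With the mean GC of all transcripts it was lost (median 0.19, adjusted p = 0.224). Cullin and neddylation core genes numbered 19 higher and 5 lower of 27 tested (19 higher and 5 lower adjusted over the list alone), and 10 higher and 12 lower with the GC offset. For cullin core genes the median log2 fold change was 0.69 (camera adjusted p = 0.0152, and adjusted p = 0.233 with an estimated correlation). The call on this list was lost under the offset (median -0.14, adjusted p = 0.913), where the test's direction was up and the median negative. CUL7 was lower (-2.88, -1.58), and CUL5 (2.52, 0.55), CUL2 (2.14, 0.48) and DCUN1D1 (3.04, 0.71) were higher. Substrate receptors of cullin ligases numbered 18 higher and 9 lower of 30 tested (18 higher and 9 lower adjusted over the list alone), and 7 higher and 12 lower with the GC offset. For cullin receptors the median was 0.52 (camera adjusted p = 0.0993), and -0.13 with the offset (adjusted p = 0.71). Without a filter on low counts it passed (median 0.56, adjusted p = 0.022). With the main filter and an estimated correlation it did not pass (adjusted p = 0.5263, and 0.8135 with the offset). FBXL5 was higher (1.64, 0.24), and FBXO22 (1.76, -0.06), CRBN (1.87, 0.15) and SOCS6 (1.73, -0.05) were higher without the offset and not with it. FBXO22 and SOCS6 kept their calls with GC and length and with the mean GC of all transcripts, and CRBN did not.

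Apoptosis genes went both ways. Pro-apoptotic genes numbered 10 higher and 12 lower of 26 tested (10 higher and 12 lower adjusted over the list alone), and 12 higher and 6 lower with the GC offset. Without the offset their median was -0.28, the mean 0.03 and the test's direction up (camera adjusted p = 0.71). Among pro apoptotic the offset gave a median of 0.38 (adjusted p = 0.0255, and adjusted p = 0.357 with an estimated correlation). With GC and length it did not pass (adjusted p = 0.0716). PMAIP1 (2.38, 0.50) and cytochrome c, CYCS (1.94, 0.73), were higher and BOK (-2.41, -0.62) was lower. Anti-apoptotic genes numbered 8 higher and 1 lower of 13 tested (8 higher and 1 lower adjusted over the list alone), and 7 higher and 1 lower with the GC offset. For anti-apoptotic genes the median was 0.69 (camera adjusted p = 0.0993), and 0.55 with the offset (adjusted p = 0.151). Without a filter on low counts this list passed (median 0.73, adjusted p = 0.0142). With the main filter and an estimated correlation it did not pass (adjusted p = 0.403, and 0.357 with the offset). BIRC3 (4.49, 2.33) and BIRC6 (1.15, 0.19) were higher, although BIRC6 was -0.65 with the mean GC of all transcripts. BIRC3 was 0.83 (adjusted p = 0.0755) in limma on log2(FPKM + 1) without a filter. XIAP (1.64, 0.01) and BAG4 (1.30, -0.17) were higher without the offset and not with it. XIAP kept its call with GC and length, where BAG4 lost it. Both kept their calls with the mean GC of all transcripts. ATF4 and integrated stress genes numbered 9 higher and 12 lower of 27 tested (9 higher and 12 lower adjusted over the list alone), and 11 higher and 13 lower with the GC offset. Median (0.02) and mean (-0.21) differed in sign (camera adjusted p = 0.486, with the offset median -0.11, adjusted p = 0.517, mean 0.06). DDIT3, the stress transcription factor CHOP, rose (2.71, 3.05), whereas the amino acid genes CTH (-2.57, -3.63), SLC7A5 (-3.15, -1.67) and PHGDH (-2.06, -0.81) fell. Endoplasmic reticulum chaperones numbered 10 higher and 11 lower of 24 tested (10 higher and 11 lower adjusted over the list alone), and 8 higher and 12 lower with the GC offset. Chaperones had a median of 0.09 against a mean of -0.10 (camera adjusted p = 0.753, with the offset median -0.23, adjusted p = 0.332). HYOU1 (-2.17, -1.25) and P4HB (-2.01, -0.75) were lower and DNAJB9 (2.20, 0.79) and DNAJC3 (1.89, 0.40) higher. Autophagy and lysosome genes numbered 13 higher and 16 lower of 30 tested (13 higher and 16 lower adjusted over the list alone), and 9 higher and 11 lower with the GC offset. For lysosomal genes the median was -0.47 (camera adjusted p = 0.184), and -0.10 with the offset (adjusted p = 0.682). Falls included ATG9A (-2.55, -1.17), CTSA (-2.27, -1.08) and CTSD (-2.87, -1.21). Drug efflux genes numbered 1 higher and 4 lower of 8 tested (1 higher and 4 lower adjusted over the list alone), and 0 higher and 4 lower with the GC offset. For efflux genes the median was -0.46 (camera adjusted p = 0.284), and -1.02 with the offset (adjusted p = 0.059). With the replicate block beside the offset the list passed (median -1.02, adjusted p = 0.0324). With an estimated correlation and no block it did not pass (adjusted p = 0.643, and 0.427 with the offset). ABCC1 (-1.76, -0.86), ABCC3 (-2.48, -1.48) and ABCB4 (-3.09, -3.55) were lower and ABCG2 was higher without the offset and not with it (1.26, -0.01). ABCG2 kept its call with the mean GC of all transcripts and lost it with GC and length.

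Muscle markers, a list of another lineage, were mostly lower. They numbered 0 higher and 4 lower of 5 tested (0 higher and 4 lower adjusted over the list alone), and 0 higher and 4 lower with the GC offset. For muscle markers the median log2 fold change was -3.70 (camera adjusted p = 0.0153, and adjusted p = 0.233 with an estimated correlation). Among muscle markers the offset gave a median of -2.51 (adjusted p = 0.0019, and adjusted p = 0.16 with an estimated correlation). MYH8, a myosin heavy chain, went from 99.2 ± 6.88 to 2.94 ± 0.849 CPM (-5.07, -5.18), and DES (-4.10, -2.51), ACTC1 (-3.70, -4.23) and ACTA1 (-3.03, -1.75) were lower. Epithelial markers numbered 0 higher and 7 lower of 8 tested (0 higher and 7 lower adjusted over the list alone), and 0 higher and 5 lower with the GC offset. For epithelial markers the median log2 fold change was -2.32 (camera adjusted p = 0.0232, and adjusted p = 0.475 with an estimated correlation). Its call was lost under the offset (median -1.21, adjusted p = 0.136). KRT8 (-2.27, -0.96), KRT18 (-1.86, -0.43), KRT5 (-4.14, -3.05) and CLDN7 (-3.53, -2.52) were lower. Endothelial markers numbered 1 higher and 2 lower of 6 tested (1 higher and 2 lower adjusted over the list alone), and 1 higher and 4 lower with the GC offset. For endothelial markers the median was -0.42 (camera adjusted p = 0.247), and -0.83 with the offset (adjusted p = 0.355). TIE1 (-2.93, -1.47) and VWF (-4.42, -3.17) were lower and ESAM (1.15, 2.31) was higher, although ESAM was 0.37 (adjusted p = 0.0742) in limma on log2(FPKM + 1) without a filter. Immune markers numbered 0 higher and 4 lower of 8 tested (0 higher and 4 lower adjusted over the list alone), and 0 higher and 3 lower with the GC offset. For immune markers the median was -0.70 (camera adjusted p = 0.575), and -0.17 with the offset (adjusted p = 0.764). Without control replicate 1 the median was 0.04. CD3E was lower (-2.86, -2.32), and CD68 (-1.09, -0.14) and CSF1R (-0.82, 0.32) were lower without the offset and not with it. CD68 kept its call with GC and length and lost it with the mean GC of all transcripts. CSF1R lost its call in each of the limma fits on FPKM (adjusted p = 0.101 to 0.19). CD74 had 84 counts over the controls and 3 over the knockdown libraries, a ratio of 28 with an exact 95% interval of 9.24 to 138. Without knockdown replicate 0, which held 2 of those 3 counts, the ratio for CD74 was 53.8 (9.4 to 2150). Neural markers numbered 0 higher and 3 lower of 8 tested (0 higher and 3 lower adjusted over the list alone), and 1 higher and 3 lower with the GC offset. For neural markers the median was -0.32 (camera adjusted p = 0.435), and 0.05 with the offset (adjusted p = 0.37). The mean with the offset was -0.46. S100B (-2.31, -1.79) was lower and TUBB3 was lower without the offset only (-1.49, 0.08). Without knockdown replicate 1 S100B was -3.35, and without knockdown replicate 0 CD3E was -3.74. Adipocyte markers, with 4 tested members and so no list test, numbered 2 higher and 2 lower of 4 tested (2 higher and 2 lower adjusted over the list alone), and 0 higher and 1 lower with the GC offset. PLIN4 was lower (-2.90, -1.37), and FABP4 (1.30, -0.53), PPARG (0.62, -0.17) and PLIN1 (-1.38, -0.39) were called without the GC offset and not with it. PLIN1 also lost its call under DESeq2 (adjusted p = 0.0856) and without a filter on low counts (adjusted p = 0.0538). Without knockdown replicate 0 PLIN4 was -3.50. With GC and length PLIN4 was -1.07 (adjusted p = 0.0513), FABP4 -1.05 (adjusted p = 0.00243) and PPARG -0.37 (adjusted p = 0.011). Abundant noncoding RNAs, also with 4 tested members, numbered 2 higher and 2 lower of 4 tested (2 higher and 2 lower adjusted over the list alone), and 4 higher and 0 lower with the GC offset. MALAT1 (3.23, 1.81) and NEAT1 (1.99, 1.23), nuclear long noncoding RNAs, were higher, and SCARNA2 (-0.49, 1.27) and TERC (-0.76, 1.08) were called in opposite directions. NEAT1 was not past the threshold in limma on log2(FPKM + 1) (adjusted p = 0.416), and TERC was not without control replicate 0 (adjusted p = 0.0788) or with GC and length (adjusted p = 0.142).

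Among expressed genes, leaving out symbols of clones, pseudogenes and antisense RNAs, the largest rises without the GC offset were those of ESM1 (6.50, 5.03), MYCT1 (4.89, 3.13), MYH16 (4.74, 5.57), which the annotation gives as a transcribed unitary pseudogene, SERPINB2 (4.56, 3.26), the hyaluronan synthase HAS2 (4.34, 2.41), KBTBD8 (4.29, 2.32), ZNF92 (4.13, 1.90), the collagenase MMP1 (4.10, 3.20), EVI2A (4.07, 1.92) and HMMR (3.75, 1.69). MMP1 averaged 20.3 ± 1.06 CPM in the controls and 348 ± 184 CPM after knockdown (mean ± SD, n = 3 each), with 136 CPM in knockdown replicate 2. SERPINB2 was at 94.7, 87.9 and 16.6 CPM in knockdown replicates 0, 1 and 2. The 10 largest falls were COL2A1, COL9A1, COMP, HIST2H3D, HIST1H4D and HIST1H4L, given above, with PRELP, a cartilage leucine-rich proteoglycan (-8.27, -7.51), ALPG (-8.04, -6.48), which has near-identical paralogs, the cartilage protein matrilin 1, MATN1 (-6.98, -6.12), and the type IX collagen chain COL9A2 (-6.82, -5.08). Without knockdown replicate 0 PRELP was -9.14, and without knockdown replicate 1 COL9A2 was -7.93. The 5 smallest p-values belonged to COL2A1, COL9A1, COL1A2, ALPG and ACAN. By the same size rule with the GC offset, applied after seeing the data, the inducible HSP70 genes HSPA1A (2.03, 3.39) and HSPA1B (2.16, 3.44), near-identical copies, joined the rises with ZFAND2A (2.77, 3.23), MYEOV (2.91, 4.06) and MRGPRX4 (3.49, 4.04). Among falls it added the matrix Gla protein MGP (-5.40, -7.01) and IGFBP5 (-6.63, -6.13).

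Of 41 lists tested, 19 passed camera with the preset correlation without the offset and 19 with it, 15 of them in both and in the same direction. With an estimated correlation 0 lists passed limma's camera without the offset, 8 had an unadjusted p under 0.05, and fry passed 33; with the offset the cartilage matrix list alone passed. On genes with whole counts only, chosen after seeing the data, the call on fatty acid genes ended with a median of -0.01 (adjusted p = 0.523). Calls also ended, with fewer members tested, for heat-shock (median 1.86, adjusted p = 0.0771), ribosomal protein (median 0.48, adjusted p = 0.0914) and glycolysis genes (median -0.72, adjusted p = 0.154). The same held for cholesterol (median -0.71, adjusted p = 0.153), TGF-beta target (median -0.68, adjusted p = 0.562) and YAP target genes (median -0.59, adjusted p = 0.39). Camera on ranks passed 15 lists, and calls ended for cholesterol (adjusted p = 0.0899), fatty acid (0.144), muscle (0.0696) and TGF-beta target genes (0.116). Under the offset from the mean GC of all transcripts, calls ended for mitotic (median 0.21, adjusted p = 0.0865), proteasome (median 0.23, adjusted p = 0.226), mitochondrially encoded (median 0.53, adjusted p = 0.226) and YAP target genes (median -0.54, adjusted p = 0.121), as they did for the repair, histone, cullin core and epithelial lists. With GC and length, calls ended for mitochondrially encoded genes (median 0.31, adjusted p = 0.655), proteasome subunits (median 0.16, adjusted p = 0.0947), TGF-beta and YAP targets, and the cullin core (adjusted p = 0.836) and epithelial lists (adjusted p = 0.0692). Lists that passed under one of these offsets and not without were the anti-apoptotic (adjusted p = 0.0391 with GC and length and 0.0297 with mean GC), NRF2 target (0.0172 with GC and length) and G1 cyclin lists (0.0167 with mean GC), beside the pro-apoptotic, AP-1 and ribosome biogenesis lists. Counts that were not whole in some library, and so shared reads, included those of MDM2, FAS, HSP90AA1, DDIT3, SREBF1 and AXIN2.

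**Figure D4:**
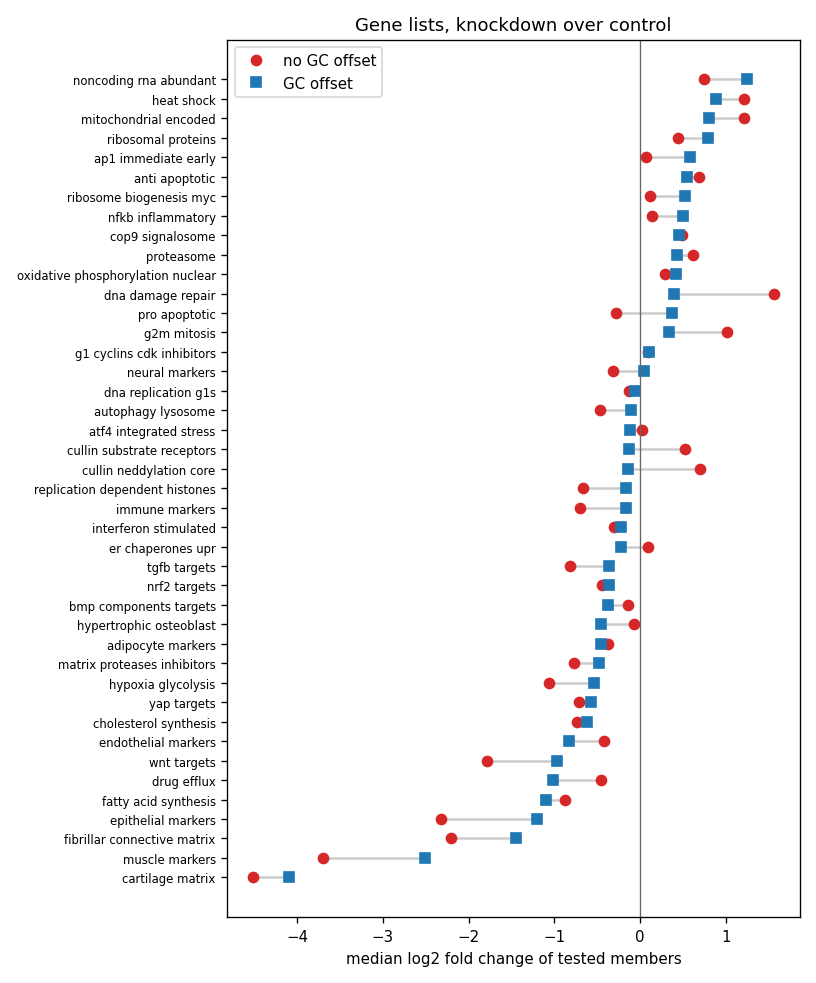
Median log2 fold change (knockdown over control) of the tested members of each gene list reported here, without (circles) and with (squares) the GC offset. Cartilage matrix is lowest in both, at -4.51 and -4.10.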

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

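The GC offsets, protein-coding genes only and whole counts only were chosen after the result was seen. Under RLE or upper-quartile factors, library totals, other filters, DESeq2 and limma on FPKM, the direction and side of the threshold of COPS5 and the counts of changed, higher and lower genes stayed within 1.5 times, and the exception among these settings was the count of 2-fold changes, 6941 in limma on log2(FPKM + 1), where log2(FPKM + 0.1) gave 7959, and the cause was not tested. Without 1 library at a time, 14267 to 15069 genes passed, 6831 to 7221 higher and 7297 to 7848 lower, 10574 to 10961 changed at least 2-fold, 17 to 20 lists passed, and COPS5 was -0.64 to -0.47. DESeq2 gave no adjusted p for 30496 genes, which were left uncounted. Library totals moved the median log2 fold change of all genes to 0.107. At 24940941 to 30282205 fragments, genes with few counts such as CD74 and HIST2H3D have wide counting intervals.

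Changes of at least 2-fold numbered 5786 with the GC offset, 5299 with GC and length, 5925 with the mean GC of all transcripts and 5593 with the GC offset and block, and the cause was not tested beyond the removal of the trend itself. With whole counts only, where 12004 genes were tested and COPS5 was not, 9516 genes passed, 4610 higher and 4906 lower, 6827 at least 2-fold, and 10 lists passed; fewer genes were tested by construction. Camera with an estimated correlation passed 0 of 41 lists (8 at an unadjusted p under 0.05), and 1 with the GC offset; fry passed 33 and, with the GC offset, 34.

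With the replicate number as a block, 14363 genes and 20 lists passed and COPS5 was -0.55. Deviations of libraries with the same number correlated at -0.115, -0.116 and 0.048 across genes, so the labels share a number and no pairing was used, and not every library correlated best with its own number. The block ended the call of PLIN1 and brought the anti-apoptotic list past the threshold (adjusted p = 0.045). Beside the GC offset it brought the efflux list past it (adjusted p = 0.0324) and ended the call of BIRC6 (adjusted p = 0.0669).

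The following log2 fold changes or list directions were reversed, and the cause was not tested. For lists the direction is that of the set test, which can turn while the median given here keeps its sign. COPS7B was 0.00 with library totals and 0.02 in each of the limma fits on FPKM. The NF-kappaB list had a median of -0.30 with the stricter filter, 0.13 without knockdown replicate 0 and 0.14 with fry. Without knockdown replicate 2 the hypertrophic and osteoblast list was 0.02 and the interferon list -0.18, and with whole counts only the interferon list was -0.28. Medians of lists not past the threshold also changed sign without 1 library, with the direction of the test kept. Without knockdown replicate 2 they were -0.11 for AP-1, -0.06 for ATF4, -0.02 for G1 and -0.08 for ribosome biogenesis genes. The osteoblast list was 0.06 without control replicate 0 and immune markers were 0.04 without control replicate 1. Over the fits that each left out 1 library, the medians ranged from 0.13 to 0.72 for the NF-kappaB list, -0.19 to 0.06 for the osteoblast list and -0.38 to -0.18 for the interferon list. The GC offset gave GPS1 0.02, COPS4 -0.27, COPS7A 0.48, COPS7B 0.42, COPS8 -0.05, FBXO22 -0.06, SOCS6 -0.05, RB1 -0.52, CCND3 0.30, BAG4 -0.17, SMAD5 -0.14, ABCG2 -0.01, SCARNA2 1.27, TERC 1.08, CSF1R 0.32, FABP4 -0.53, PPARG -0.17, TUBB3 0.08, the AP-1 immediate early list 0.57, the ATF4 integrated stress list -0.11 and the cullin substrate receptors list -0.13. GC and length together gave COPS4 -0.51, COPS7A 0.35, COPS7B 0.38, RB1 -0.32, CCND3 0.16, PSMC6 -0.03, PSMA3 -0.26, SDHD 0.00, SCARNA2 0.56, TERC 0.42, CSF1R 0.45, FABP4 -1.05, PPARG -0.37, the AP-1 immediate early list 0.76 and the ATF4 integrated stress list -0.04. The mean GC of all transcripts gave COPS4 -0.26, COPS7A 0.64, COPS7B 0.19, COPS8 -0.12, CCND3 0.28, BIRC6 -0.65, IFIT5 -0.10, NFKB2 0.05, PHEX -0.04, PSMA3 -0.04, PSMA4 -0.11, SCARNA2 1.28, TERC 1.09, CSF1R 0.38, FABP4 -0.67, PPARG -0.04, TUBB3 0.06, the AP-1 immediate early list 0.82 and the ATF4 integrated stress list 0.00. The GC offset with the block gave GPS1 0.02, COPS4 -0.27, COPS7A 0.47, COPS7B 0.42, COPS8 -0.05, FBXO22 -0.06, SOCS6 -0.05, RB1 -0.53, CCND3 0.29, BAG4 -0.17, SMAD5 -0.14, ABCG2 -0.02, SCARNA2 1.26, TERC 1.11, CSF1R 0.25, FABP4 -0.52, PPARG -0.17, TUBB3 0.08, the AP-1 immediate early list 0.58, the ATF4 integrated stress list -0.14 and the cullin substrate receptors list -0.13. Under the GC offset with an estimated correlation the medians were the AP-1 immediate early list 0.57, the ATF4 integrated stress list -0.11 and the cullin substrate receptors list -0.13, and with fry the AP-1 immediate early list 0.57, the ATF4 integrated stress list -0.11, the cullin neddylation core list -0.14 and the cullin substrate receptors list -0.13.

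Of 235 single genes and lists, the GC offset kept 180 calls in the same direction, turned 6, ended 25 and added 6, and 18 were past the threshold in neither fit. GC and length ended 22 and the mean GC of all transcripts 27. COPS7A lost its call without each of the controls and without knockdown replicates 0 (adjusted p = 0.107) and 1 (adjusted p = 0.178). CSF1R lost it without control replicate 0 or 2 or knockdown replicate 0, and PLIN1 without control replicate 0 or knockdown replicate 0 or 2. TERC lost it without control replicate 0 or 1 or knockdown replicate 1 or 2. The anti-apoptotic list passed without knockdown replicate 2 (adjusted p = 0.0266).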

Other observations

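Among the tests here, those of GC bias, codon use, the GC trend of the cartilage list and of pseudogenes, and the other splits of the libraries were chosen after the result was seen. Most processed pseudogenes matched to an abundant parent gene were lower after knockdown relative to that parent, the gene whose symbol they carry. For 585 processed pseudogenes whose parent gene had a mean of at least 100 CPM, the median change of the log2 ratio of copy to parent was -3.45, and with the GC offset 493 of them had a lower ratio. For the 43 unprocessed copies of such parents the median was 0.27, and 19 had a lower ratio with the GC offset. All pseudogenes together took 0.53% to 0.55% of fragments in the controls and 0.41% to 0.46% after knockdown. This summed share fell far less than the median ratio, but it covers pseudogenes of every type and is not a ratio to parents. The median change of the 585 processed copies themselves was -3.33 with the GC offset. Copies were not filtered by their own level beyond the general filter, so some may have few counts. Long intergenic, antisense, sense intronic and other long noncoding RNA classes together took 0.99% to 1.07% of fragments in the controls and 2.13% to 2.91% after knockdown. Among genes that Cuffdiff had not skipped, the 10 most abundant took 5.43% to 5.86% in the controls and 3.31% to 3.88% after knockdown. All these shares leave out the skipped genes, EEF1A1 and ACTB among them.

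The dependence of fold changes on transcript GC content held in most of the classes of untranslated RNA examined. In lincRNA genes the slope was -1.17 log2 units per 10% GC against -1.42 in protein-coding genes, -0.93 in antisense and -1.41 in sense intronic genes. In 519 processed pseudogenes it was -1.27 ± 0.236 (SE). In the 66 genes annotated as miscellaneous RNA, mostly copies of 7SL and 7SK RNA, it was 0.10 ± 0.309 (SE). The lincRNA slope argues against codon use or translation as the source. Regional transcription is argued against by the GC content of the 10 nearest genes, with a coefficient of 0.06 beside -1.45 for the gene's own. A GC-dependent bias of library making or sequencing remains a possible explanation, since the same lincRNA slope of -1.17 is what it needs. The miscellaneous RNAs showed no such slope. Being mostly copies of 7SL and 7SK RNA, they are a weak test of whether a bias acts alike on every class. The knockdown itself stays open and untested, because every library of a group shares the sign of the slope.

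Lower cartilage matrix expression was not accounted for by the GC trend, as the list median was -4.10 with the GC offset and -4.51 without it. Cells of a karyotype that differed in many chromosome arms would spread the medians of chromosome stretches. The SD of 38 stretch medians was 0.073, under the 95th percentile of 0.081 for shuffled genes, which argues against that. Stretches were split at the longest gap between genes, not at known centromeres, so they need not be arms. Their medians ran from -0.141 to 0.183. A single SD cannot show a difference in few arms, so that case stays open. Of the 5 lists of other lineages tested, muscle had a median of -3.70 (-2.51 with the offset; adjusted p = 0.233 and 0.16 with an estimated correlation) and epithelium -2.32 (-1.21, not past the threshold; adjusted p = 0.475 and 0.419). Endothelial (-0.42), immune (-0.70) and neural markers (-0.32) did not pass camera. Fry, which passed 33 of 41 lists, passed all of them (adjusted p = 0.000147, 0.00336 and 0.000463, and 0.000652, 0.0245 and 0.0013 with the offset). Camera compared each list with all other genes and fry asked only whether its members changed, so neither compared a list with cartilage. With 76.2% of tested genes called, a pass in fry says little about a lineage. All 19 tested cartilage genes were lower, against 2 of 6 endothelial, 4 of 8 immune and 3 of 8 neural markers (4, 3 and 3 with the offset). Lower expression was also seen in some lists beside cartilage, with 4 of 5 muscle and 7 of 8 epithelial markers lower. A subpopulation of the same line with the same karyotype could give such a change and was not tested. An effect of JAB1 loss on these genes stays open as a hypothesis. The design cannot tell it from anything else that the libraries of a group share, such as the hairpin used or a common preparation.

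For the pseudogenes, the GC trend is argued against by a median ratio change of -3.59 with the GC offset. Reads of abundant parent genes placed on their copies may contribute, but the test could not tell. The median ratio change for parents of at least 100 CPM was higher by 0.18 log2 units than that of the 41 copies of parents under 10 CPM, with a 95% bootstrap interval (2000 resamples of genes, added after the result was seen) of -2.11 to 2.48. The copies of low parents are too few and too spread to decide, and no biological explanation was tested.

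The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split, the 1 of 10 with a count as large in each case, gave 14692 changed genes, 7151 higher, 7541 lower and 10594 at least 2-fold, where the highest other split gave 0 by edgeR (up to 59 at an unadjusted p under 0.05). With the GC offset it gave 11939 genes against 0 (up to 121 unadjusted). Each other split mixes control and knockdown libraries on both sides, so the difference between the groups adds to its spread. Few gene calls in those splits were thus given in advance, and these counts do not exclude chance. Of lists, tested on the splits without the offset alone, the real split passed 19 and the others 6 to 11. Camera with the preset correlation thus passed lists in every mixed split, where 0 genes were called.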
